A study of Mus musculus with 6 samples.

How the data were processed

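Total RNA of 6 neurosphere cultures was measured by RNA-seq, 3 with the genotype label ACVR1 G328V and 3 with the label ACVR1 WT. Per the labels' protocols, RNA was isolated with a column kit, ribosomal RNA was depleted, a stranded library kit was used and paired ends were read on a HiSeq4000. The labels name both a TruSeq and a Pico kit without saying which libraries each served. Groups were taken from the genotype in the labels. The labels describe biological replicates but not the animals or cultures behind them, so p-values measure the spread between these samples. Replicate numbers follow the labels, and WT has the numbers 1, 3 and 70A.

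The submitters' processing notes name the build mm10 and the tools FastQC 0.11.3, TopHat2 2.0.13 and Bowtie2 2.2.1, and the role of each is not given in the sources used here. The deposited HTSeq table holds whole-number counts per gene symbol for 17551 genes, not normalized, with no row summing to less than 2 and 0 rows that name no gene. The deposited Cufflinks table holds estimated counts of fragments for 23107 genes, including all 17551. The counting settings, the use of strand and the annotation are not given in the sources used here, so overlapping or antisense genes, such as Xist and Tsix, and genes with near-identical copies, such as histone genes, are uncertain. The median ratio of HTSeq to Cufflinks values was 1.95 to 1.96 in every library over 8924 genes with at least 500 counts in each, close to 2 counts for each fragment. Counts are therefore not independent molecules.

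The HTSeq totals were 158525015, 115953495 and 182626231 in G328V replicates 1, 2 and 3, and 120457925, 191115532 and 185786938 in WT replicates 1, 3 and 70A. At these depths the spread between libraries limits the precision of most genes more than counting error does, and floors of 3 counts cover counting error only. Rn45s, the ribosomal RNA precursor, took 3.16% to 10.7% of counts. Mitochondrially encoded and cytosolic ribosomal protein genes had 0 tested members and were not analysed here. No pair of libraries was close to a duplicate, the smallest chi-square per degree of freedom being 1419.

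Counts were tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F-test (legacy fit, robust, TMM factors, filterByExpr with a minimum count of 10) for G328V against WT, with no covariate, and Benjamini-Hochberg adjustment over 14643 genes. CPM values use TMM-scaled library sizes. Standard errors of log2 differences were derived from the F statistic. DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives, and an adjusted p that DESeq2 left as NA stayed NA (1030 genes). Estimated counts of the Cufflinks table were rounded to whole numbers before the same edgeR test.

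The design, the alternatives, the naming rule and 38 gene lists were fixed before the data were examined. The lists covered BMP targets, BMP receptors and ligands, TGF-beta targets, neural, glial and other cell types, cell cycle, stress and signalling pathways, patterning genes and sex-linked genes. The 34 lists with at least 5 tested members, sex-linked genes left out, were tested with camera (preset correlation 0.01, and estimated) and fry, with adjustment over the 34 lists. Named genes were Acvr1, Id1, Id2, Id3, Smad6 and Smad7. They also included the 8 largest rises and 8 largest falls among genes past the FDR with at least 10 CPM on average, groups that did not overlap and a symbol that is not a predicted, clone or small RNA name. From each described list the up to 3 members with the smallest adjusted p, ties by size, were named. A single gene that this rule names was left out and is not reported here. The rule found 0 genes among edgeR's calls, so it was also applied to DESeq2's calls after the results were seen. The list levels in the plot of gene lists use log2 CPM with a prior count of 2.

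The tests of genes and of lists were tested on simulated data. Counts for 14643 genes were drawn from the means, library sizes and dispersions of G328V against WT, with 200 genes changed, 50 at each size. For this comparison edgeR recovered 10% of 4-fold, 62% of 16-fold, 76% of 64-fold and 86% of 256-fold changes with 4 false calls, and limma-voom recovered 8%, 46%, 60% and 74% with 4 false calls. DESeq2 recovered 42%, 86%, 88% and 96% with 140 false calls among 296. These rates hold for data with many large changes, where edgeR made 121 calls, and do not carry over to data with 0 calls. In the real data Xist and Ddx3y, with edgeR log2 differences of 9.72 and -11.3, had adjusted p-values of 0.254 and 0.718. Thus 0 calls by edgeR do not argue against very large changes. With no gene changed, edgeR, limma-voom and DESeq2 called 0, 0 and 101 genes, and camera called 0 lists. Each setting was drawn once, with dispersions that edgeR estimated, so the false calls do not compare the tools on equal terms. Each gene was drawn independently of the others in these simulations. Members of the real lists can be correlated, with an estimate of 0.607 for histone genes. The simulated 0 therefore does not show how often camera calls correlated lists falsely. With the BMP list simulated 4-fold higher, its camera adjusted p was 1.77e-10 with the preset correlation and 0.0587 with an estimated one.

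Alternatives were other scaling factors, other filters, other tools, the Cufflinks table, a replicate block, stricter thresholds and each library left out. Positions of 117 of the 123 genes that the naming rule covers were found in RefSeq for GRCm38, the assembly behind mm10. The codon of the replaced glycine was placed with the GENCODE M21 annotation. The 6 samples were also split into 3 and 3 in all 10 ways. Since 3 against 3 samples cannot give a share of splits under 0.1, an exact permutation test cannot reach p = 0.05 here.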

Results

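RNA was sequenced from mouse neurospheres, free-floating cultures of neural stem and progenitor cells grown with EGF and FGF, on a C57BL/6 background. The 3 G328V libraries came from neurospheres with the genotype label ACVR1 G328V, and the 3 WT libraries from neurospheres with the label ACVR1 WT. G328V names a glycine-to-valine change in Acvr1, a type I receptor for bone morphogenetic proteins (BMPs). The series describes 3 biological replicates per group. Total gene counts ranged from 115953495 in G328V replicate 2 to 191115532 in WT replicate 3. The comparison asked which genes differed in expression between neurospheres labelled G328V and WT.

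Acvr1 had higher counts in each of the 3 G328V libraries than in any WT library. Its level was 381 ± 233 CPM (SD, n = 3) in G328V and 77.7 ± 30.9 CPM (SD, n = 3) in WT. The 3 G328V libraries held 244, 250 and 650 CPM, and WT replicates 1, 3 and 70A held 42.4, 100 and 90.7 CPM. The log2 difference was 2.29 with a standard error of 0.55, and it did not pass edgeR's test over 14643 genes (adjusted p = 0.997). DESeq2, run as an alternative, gave 2.27 with an adjusted p of 0.0291, and the adjusted p ranged from 0.0254 to 1.0 over 19 alternative settings. Acvr1 lies on chromosome 2 from 58446438 to 58566828 (GRCm38), on the minus strand. In the reference gene, the codon of the glycine that G328V replaces lies in a coding exon at 58462963 to 58462965. The genotype label names the change but not the locus that carries it. Gene counts do not tell mutant from wild-type Acvr1. Counts per fragment for Acvr1 were 1.18 in G328V and 1.94 in WT, so the G328V values rest on fewer counts for each fragment.

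BMP-SMAD1/5 target genes rose as a list in G328V, with a median log2 difference of 2.61 over 16 tested members. Positive differences were found for 14 members, and in 9 members the groups did not overlap, each with G328V higher. Chance gives groups that do not overlap, in either direction, for 10% of genes. Smad6, an inhibitory SMAD that BMP signalling induces, averaged 53.7 ± 14.6 CPM (SD, n = 3) in G328V and 4.39 ± 3.17 CPM in WT. Smad9, which encodes a SMAD of the BMP branch, averaged 24.2 ± 5.16 CPM in G328V and 0.245 ± 0.286 CPM in WT. Id1, Id2 and Id3, which encode inhibitors of basic helix-loop-helix factors, had log2 differences of 2.70, 2.02 and 2.82 with standard errors of 1.40, 0.86 and 0.85. Their unadjusted edgeR p-values were 0.0999, 0.0563 and 0.0152, and DESeq2 called none of the 3 (adjusted p = 0.592, 0.523 and 0.0936). Id1 was at 0.601 CPM in WT replicate 1, against 67.2 and 61.9 CPM in WT replicates 3 and 70A. Id2 was at 87.8 CPM in G328V replicate 1 and at 78.3 CPM in WT replicate 1. Smad7, another inhibitory SMAD, had a log2 difference of 1.53 with a standard error of 1.00, its groups overlapped, and the difference was 0.97 without WT replicate 1. Msx2, a homeobox gene, differed by 4.57 with a standard error of 1.28, and Nog, which encodes a secreted BMP antagonist, by 5.20 with a standard error of 2.00. None of the 16 members passed edgeR's FDR over all genes, while 9 had an unadjusted p under 0.05. Adjusted over the list alone, 5 members passed, all higher: Id3, Smad6, Smad9, Msx2 and Bambi, a BMP pseudoreceptor named after its values were seen. DESeq2 called 4 members higher over all genes. The camera set test with a preset correlation gave an adjusted p of 2.31e-17. With an estimated correlation the call was lost (adjusted p = 0.0769). The sex-linked genes Xist and Ddx3y separated the same 6 libraries completely, as given with the libraries that stood apart.

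**Figure D1:**
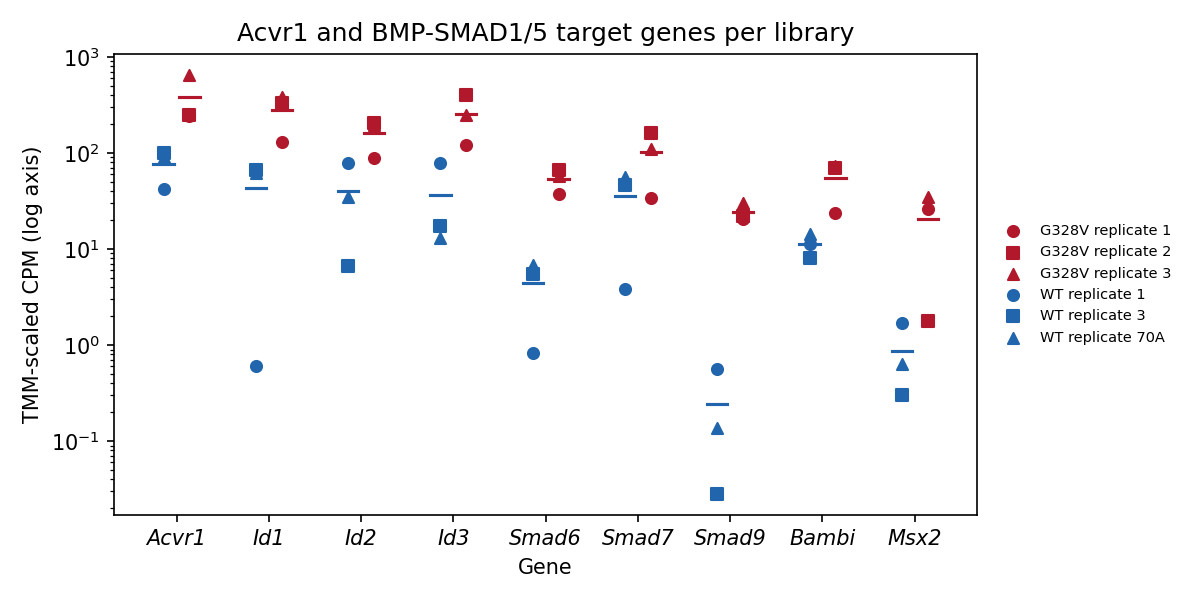
TMM-scaled CPM (logarithmic axis) of Acvr1 and 8 BMP-SMAD1/5 target genes, with 1 point per library and a short line at each group mean. Smad9 lay at 20.5 CPM or more in the 3 G328V libraries and at 0.569 CPM or less in the 3 WT libraries, while the groups overlapped for Smad7.

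A further 5 lists were higher in G328V by camera with the preset correlation, and none of their members passed edgeR's FDR over all genes or adjusted over the list alone. The real grouping called 6 lists in all, and 7 of the 9 other splits of the samples into 3 and 3 called more. Hox and hindbrain patterning genes, the transcription factors that set position along the body axis, had a median log2 difference of 1.90 over 18 members (adjusted p = 5.62e-05). With an estimated correlation its adjusted p was 0.886. Hoxc9 had 300, 14 and 51 counts in the G328V libraries and 0 in each WT library, so most of its counts came from G328V replicate 1. With Hoxc9 set to its bound against a floor of 3 counts over the WT group, the list median was also 1.90. Hoxd3 and Hoxd10 had log2 differences of 3.16 and 3.11 with standard errors of 2.45 and 2.72, and the groups overlapped for both. Hoxd3 had 0, 143 and 200 counts in G328V replicates 1, 2 and 3 and 0, 32 and 12 in WT replicates 1, 3 and 70A. Hoxd10 had 141, 0 and 109 counts in G328V and 0, 0 and 28 in WT, in the same order. Without WT replicate 70A Hoxd10 differed by 9.20, against WT libraries with 0 counts of it, so that size is not a measured value. WT replicate 3 had the lowest level of the list, and WT replicate 70A, at 0.78, lay above G328V replicate 1, at 0.75, so the groups overlapped in list level. Without WT replicate 70A or G328V replicate 2 the median was 3.30 or 1.13. Keeping only genes with at least 1 CPM in 3 libraries gave a median of 0.87, and limma-voom gave 3.49.

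Replication-dependent histone genes, which are expressed in S phase, had positive differences in all 23 members, with a median of 0.39 (camera adjusted p = 4.58e-04, and 0.886 with an estimated correlation). Hist2h2bb differed by 1.05 with a standard error of 0.43, and Hist2h3b and Hist2h2ac differed by 1.19 and 0.73 with standard errors of 0.80 and 0.60. Without G328V replicate 2 Hist2h3b and Hist2h2ac differed by 0.52 and 0.45, and without WT replicate 1 Hist2h2ac differed by 0.30. G2/M cell cycle genes had positive differences in all 22 members, with a median of 0.34 (camera adjusted p = 0.0148, and 0.886 with an estimated correlation). Bub1, a spindle checkpoint kinase, differed by 0.48, Top2a by 0.43 and Nusap1 by 0.42, with standard errors of 0.31, 0.32 and 0.30. Without G328V replicate 2 Top2a and Nusap1 differed by 0.15 and 0.18, without WT replicate 3 Top2a differed by 0.27, and without WT replicate 1 Bub1 differed by 0.22. Hypoxia and glycolysis genes had a median of 0.23 over 22 members, 16 of them positive (camera adjusted p = 0.0237, and 0.886 with an estimated correlation). Ldha and Slc2a3, a lactate dehydrogenase and a glucose transporter, differed by 1.35 and 2.03 with standard errors of 0.58 and 1.00, and Slc2a3 by 1.26 without G328V replicate 3. Adm differed by -3.89 with a standard error of 1.68, and by -0.82 without WT replicate 1, which held 146 CPM. The groups overlapped in the level of each of these 3 lists. G328V replicate 1 lay at -0.23 for histone genes, below WT replicates 3 and 70A, at 0.12 and -0.05. For G2/M genes it lay at -0.16, below the same WT libraries, at -0.08 and -0.03. For hypoxia genes WT replicate 3, at 0.30, lay above G328V replicates 1 and 3, at 0.01 and 0.29. WT replicate 1 had the lowest level of these 3 lists, and without it their adjusted p-values by camera were 0.175, 0.272 and 0.780. The calls were also lost without G328V replicate 2 (0.0562, 0.284 and 0.354) and without G328V replicate 3 (0.0516, 0.170 and 0.0664), and that of the hypoxia list without WT replicate 70A (0.0814). The median of the histone list was 0.20 without WT replicate 1 and 0.59 without G328V replicate 1, and that of the G2/M list was 0.18 without WT replicate 1 and 0.17 without G328V replicate 2. The median of the hypoxia list was 0.46, 0.12 and 0.40 without G328V replicates 1, 2 and 3, and 0.81 without WT replicate 3. With limma-voom and with total-count scaling it was 0.43 and 0.36.

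Astrocyte markers had a median log2 difference of 1.34 over 13 members, 10 of them positive (camera adjusted p = 0.0341, and 0.886 with an estimated correlation). The list level was highest in G328V replicate 1, at 1.92, where those of neural crest, neuron and myelin genes were also the highest of the 6 libraries, at 2.65, 2.199 and 1.61. The astrocyte level of G328V replicate 3, at -0.68, lay below WT replicates 1 and 70A, at -0.03 and -0.39, so the groups overlapped. Gfap, an intermediate filament of astrocytes, was at 10.1 CPM in G328V replicate 1 and at most 0.299 CPM in the other libraries. Sparcl1 was at 167 and 1666 CPM in G328V replicates 1 and 2 and at 1.05 CPM in G328V replicate 3, against 9.99 to 28.5 CPM in WT. Apoe, a lipid carrier, was at 53.4, 32.5 and 1.25 CPM in G328V and at 0.886, 0.813 and 2.95 CPM in WT. Without G328V replicate 1, WT replicate 3 or WT replicate 70A the call was lost (camera adjusted p of 0.418, 0.141 and 0.0845), and the medians were 1.32, 1.22 and 2.44. Without WT replicate 1 the median was 2.40. Total-count scaling, the 1 CPM filter and limma-voom also ended it (0.0825, 0.0636 and 0.364).

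Forebrain patterning genes and Wnt pathway genes each held members that passed in both directions when adjusted over the list alone. By fry's test for change in either direction, which does not compare a list with other genes, the adjusted p-values of forebrain genes, Wnt genes and neural stem markers were 0.00418, 5.40e-04 and 0.0458. Dlx1 and Dlx2, homeobox genes of ventral forebrain progenitors, were higher in each G328V library than in any WT library. Dlx1 lay at 21.4 to 24.3 CPM in G328V and at 1.05 to 2.97 CPM in WT, and Dlx2 averaged 62.5 ± 29.2 CPM (SD, n = 3) in G328V and 1.58 ± 0.802 CPM in WT. Adjusted over the list alone, these 2 passed as higher, and Nr2f1, named after its values were seen, passed as lower with a log2 difference of -1.43, while edgeR called 0 forebrain genes over all genes and DESeq2 called 2, Dlx1 and Dlx2, as higher. Six3 was at 24.7 CPM in WT replicate 1 and at most 1.78 CPM elsewhere. Among 20 tested Wnt pathway genes, 2 passed edgeR's test adjusted over the list alone and 0 over all genes, while DESeq2 called the same 2 over all genes, Wif1 as higher and Wnt7b as lower. Wif1, a secreted Wnt inhibitor, averaged 51.2 ± 19.4 CPM in G328V and 0.860 ± 0.951 CPM in WT. Wnt7b, a Wnt ligand, averaged 4.38 ± 3.12 CPM in G328V and 449 ± 182 CPM in WT. Fzd10 was at 24.1 CPM in WT replicate 1 and at most 0.484 CPM elsewhere. Of 13 tested neural stem markers, 10 had negative differences, and none passed adjusted over the list alone. WT replicate 1 stood apart, with a list level of 2.23 against -1.02 and -1.11 in WT replicates 3 and 70A. Fabp7 and Tnc, markers of radial glia, were at 1313 and 4056 CPM in WT replicate 1, the highest level of each. Without WT replicate 1 the log2 differences of Six3, Fzd10 and Fabp7 turned from -3.80, -5.07 and -4.14 to 2.72, 8.29 and 6.02. Their edgeR adjusted p-values were then 0.922, 0.735 and 0.661. Fzd10 had 0 counts in both WT libraries left, so the size of its 8.29 is not a measured value. Six3 had 1 and 30 counts there, against 306, 0 and 0 in G328V.

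**Figure D2:**
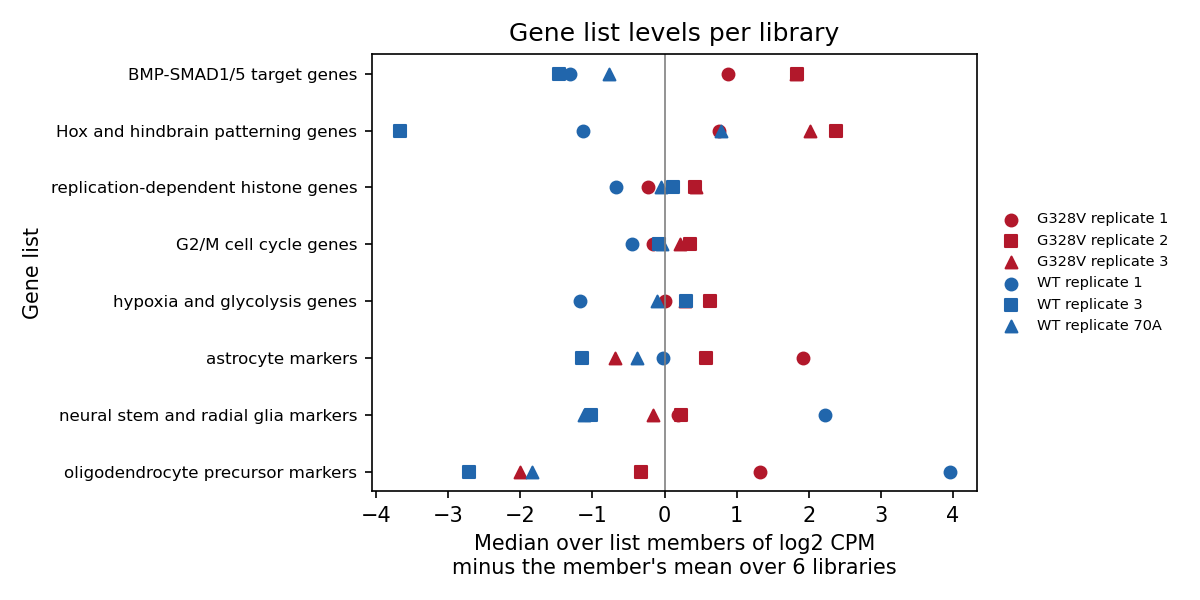
Level of 8 gene lists in each library, as the median over members of log2 CPM minus the member's mean over the 6 libraries, with 1 point per library. BMP-SMAD1/5 target genes lay at 0.88 or above in the 3 G328V libraries and at -0.78 or below in the 3 WT libraries, while WT replicate 1 lay at 2.23 for neural stem markers and at 3.95 for oligodendrocyte precursor markers.

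Over all genes, edgeR called 0 of 14643 genes at an FDR under 0.05, 0 higher and 0 lower in G328V, and 0 with at least a 2-fold change. At an unadjusted p under 0.05 it counted 594 genes, 276 higher and 318 lower, where 732 would arise with no difference. The limma-voom test also called 0 genes, with 590 at an unadjusted p under 0.05. The newer edgeR 4 fit, added after the data were seen, also called 0 genes, with 895 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0527. DESeq2 called 173 genes, 94 higher and 79 lower, 169 of them changed at least 2-fold, with 1149 of 17551 genes at an unadjusted p under 0.05. In a single draw of counts simulated with edgeR's dispersions and no change, DESeq2 called 101 of 14643 genes and edgeR called 0. That draw follows edgeR's own model, so it does not compare the tools on equal terms. Leaving out WT replicate 1, as an added alternative, raised DESeq2's count to 727 genes, of which 150 were among the 173. Without G328V replicates 1, 2 and 3 it was 283, 405 and 329, and without WT replicates 3 and 70A it was 272 and 374. Groups did not overlap for 1421 genes, 9.70% of those tested, where chance gives 10%.

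The genes that DESeq2 called with the largest differences were chosen by the planned rule applied to DESeq2's calls after edgeR had called none. Among those higher in G328V were Xist, Smad9, Wif1 and Dlx2. Daam2, a formin of the Wnt pathway, averaged 51.8 ± 28.7 CPM (SD, n = 3) in G328V and 0.528 ± 0.344 CPM in WT, with a DESeq2 adjusted p of 1.68e-13. Scg2, a secretory granule protein, and Epb4.1l3, a membrane skeleton protein, had DESeq2 log2 differences of 5.81 and 5.63, and Pcp4l1 had 5.16. Without WT replicate 1, which held 277 of the WT counts of Epb4.1l3 against 17 and 21 in the other WT libraries, its DESeq2 log2 difference was 8.59. Among those lower in G328V were Ddx3y, Uty and Wnt7b. Pcdh8, a protocadherin, was at 0.109 CPM or less in G328V, at 1.04 CPM in WT replicate 1 and at 92.3 and 125 CPM in WT replicates 3 and 70A. Igfbp4, which encodes an insulin-like growth factor binding protein, had a DESeq2 log2 difference of -4.46, with 1794 CPM in WT replicate 70A alone against 70.4 and 133 CPM in the other WT libraries. Without WT replicate 70A the edgeR log2 difference of Igfbp4 was -1.73, against -4.44 with all 6 libraries. Rgnef, Lmo1 and Syt13 had DESeq2 log2 differences of -3.95, -3.87 and -3.86. None of these passed edgeR's FDR over all genes, where the smallest adjusted p was 0.254 for Xist.

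Sex-linked genes and WT replicate 1 set libraries apart beside the groups. Xist, the RNA that coats the inactive X chromosome, had 76093, 95736 and 128424 counts in the G328V libraries and 106, 44 and 206 in the WT libraries. Ddx3y, a Y-linked gene, had 0, 1 and 6 counts in G328V and 6274, 3119 and 7122 in WT, and Uty had 2, 0 and 10 counts in G328V and 5567, 1967 and 6234 in WT. Sex-linked expression and genotype therefore could not be separated in any comparison of these groups. Olig2, a factor of the oligodendrocyte lineage, had 51237 counts in WT replicate 1 and at most 161 in any other library. Correlations of log2 CPM between libraries were 0.742 to 0.893 within WT, 0.808 to 0.863 within G328V and 0.762 to 0.888 between groups, so the 3 ranges overlapped. These correlations are across genes, which are not independent replicates.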

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

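The tests of sex, of reads shared with another locus and of library-wide mate mapping, and the DESeq2 fit without WT replicate 1, were chosen only after the result was seen.

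Acvr1 was singled out because the Cufflinks table, which the main comparison does not use, holds more fragments for it in G328V than its HTSeq counts account for. Counts per fragment were 1.18 ± 0.0393 (SD, n = 3) in G328V and 1.94 ± 7.30e-04 in WT, a difference of 0.768 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Reads shared with another locus in the reference are argued against, because the WT mean lay 0.0175 below the median of all genes. A library-wide cause is argued against too, because the group medians over all genes differed by 0.00123. Acvr1 ranked 4 among 8924 genes by this drop, as predicted for a transcript of which a mate often could not be placed on the gene. An example would be a transcript that differs in sequence from mouse Acvr1. The rank restates the drop that singled the gene out, so it adds no separate support, and the explanation stays a hypothesis. The Acvr1 log2 difference may then be understated in counts, and it was 3.05 in the Cufflinks table.

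BMP-SMAD1/5 target genes were higher in G328V with a median log2 difference of 2.61. Of the 10 splits of the 6 samples, 1 gave a median as large in size, the real one, and the highest of the other splits was 1.51, but 10 splits are too few for a share under 0.05. The data argue against WT replicate 1 alone as the source, since the median without it was 2.79, and against the scaling, since the smaller of the medians under total-count and median-of-ratios factors was 2.59. The sex of the animals cannot be told apart from genotype, because 0 libraries differed from their group in the order of Xist and Ddx3y. The mutant receptor is the explanation the design names, and it stays open beside sex and beside any other difference between the lines, which the labels do not describe and which was not tested.

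The spread between libraries of a group was large, with an edgeR common dispersion of 0.843. WT replicate 1 does not set it alone, since the dispersion without it was 0.909 times as large. Whole-chromosome shifts, as copy number differences between lines would give, made up little of the spread. Chromosome explained 1.96% of the within-group variance of log2 CPM over 13070 placed genes. This small share cannot exclude copy number differences, because a shift of a single chromosome adds little to the variance of all genes. Chromosome 14 had median deviations of -0.70, 0.46 and 0.30 in WT replicates 1, 3 and 70A. Chromosome 13 had 0.13, -0.51 and 0.42 in G328V replicates 1, 2 and 3. No other biological explanation of the spread was tested.

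DESeq2 called 173 genes, and 5 of the 10 splits called at least as many. The highest of the other splits, G328V replicates 1 and 2 with WT replicate 1 against the rest, called 853. Counts as large therefore also arose in groupings other than genotype, and what sets them was not tested. edgeR called 0 genes in all 10 splits, the highest of the other splits being 0, with 594 genes at an unadjusted p under 0.05 in the real split and up to 1441 in the others. For gene lists, 8 of the 10 splits called at least 6, and the highest of the other splits called 14. Of the 9 other splits, 7 called more lists than the real one. These 10 splits are too few for a share under 0.05.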

How the results depend on the processing

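The edgeR 4 fit, the counts divided by 2 and the DESeq2 fit without WT replicate 1 were chosen after seeing the data. Under 19 of 21 alternative settings 0 genes passed, edgeR 4, the Cufflinks table and limma-voom included. DESeq2 called 173 genes, 94 higher and 79 lower, 169 of them at least 2-fold, and without WT replicate 1 it called 727, 453 higher, 274 lower and 688 at least 2-fold. The cause was not tested on these data, although DESeq2 called 101 unchanged genes in a single simulated draw with edgeR's dispersions. Acvr1 passed only in those 2 DESeq2 fits, at 2.27 and 1.99, and kept its direction in all 19 settings, from 1.67 to 3.05. With each library left out in turn, edgeR called 0 genes each time, 0 higher, 0 lower and 0 at least 2-fold, Acvr1 ranged from 1.67 to 2.53, the count of lists from 4 to 8 and the BMP list median from 2.04 to 3.01. Closest to a call was the fit without WT replicate 1, with a smallest edgeR adjusted p of 0.0606. It had 1024 genes at an unadjusted p under 0.05, against 594 with all 6 libraries. The smallest edgeR adjusted p was 0.135 or more with any other library left out.

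The camera test called 6 lists, against 0 with an estimated correlation and 0 with fry's directional test. Neither test by fry compares a list with other genes. By fry's test for change in either direction 4 lists passed. The BMP list had fry adjusted p-values of 0.0730 in the directional test and 0.00418 in the test for either direction. The BMP list kept its call in all 15 settings of the preset correlation. With replicate numbers 1 and 3 as a block, 0 genes and 4 lists passed and Acvr1 was at 2.61, with 1 residual degree of freedom. The G2/M, hypoxia and astrocyte lists did not pass (camera adjusted p of 0.0970, 0.204 and 0.152, medians of 0.28, 0.41 and 0.49), and the Hox list median was 7.25. The BMP, Hox and histone lists kept their calls (camera adjusted p of 4.08e-08, 3.88e-07 and 0.0120). The 4 lists therefore included a list that the main fit did not call. The deviations of same-numbered samples correlated at 0.181 and 0.226, and those of other pairs at -0.323 to 0.200. With only 2 shared numbers and no shared origin in the labels, the numbers were not taken to pair the samples, and whether they do stays open. Total-count scaling moved the median of all genes from -0.004 to 0.12 and the share of higher genes among those at an unadjusted p under 0.05 from 46.5% to 64.9%, with 0 genes called in both.

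Of 825 values of 44 other named genes, 815 kept their direction. Fabp7 turned to 1.94 with limma-voom, 0.34 with the block, 6.02 without WT replicate 1 and 6.04 with DESeq2 without it. Fzd10 turned to 1.09 with limma-voom, and to 8.29 and 7.82 without WT replicate 1 by edgeR and DESeq2. Six3 turned to 2.72 and 2.75 in those fits, and Sparcl1 to -0.34 with the block. With each library left out in turn, Fabp7 ranged from -6.55 to 6.02, Fzd10 from -6.13 to 8.29 and Six3 from -13.33 to 2.72. The values 8.29 and 7.82 for Fzd10 and -13.33 for Six3 came from fits in which a group had 0 counts. Their sizes are therefore not measured values. Fabp7, Fzd10 and Six3 had their highest level in WT replicate 1. At these depths the spread between libraries limits what can be called more than the number of counts does.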

Other observations

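In all, 28 gene lists did not pass camera, 14 with a median above 0 and 14 below. Oligodendrocyte precursor markers had a median log2 difference of -1.13, and Olig1, Olig2 and Ptprz1 were at 615, 416 and 881 CPM in WT replicate 1 and at most 9.71 CPM in any other library. Oligodendrocyte and myelin genes had a median of 0.97, midbrain-hindbrain boundary genes 0.95, mural cell and fibroblast markers 0.73, neural crest and Schwann cell markers 0.64 and neuron markers 0.51. Endothelial markers had a median of 0.18 and microglia and macrophage markers 0.11, while ependymal and motile cilia genes had -0.15 and 3 choroid plexus and erythroid markers, too few for a set test, had 1.78. Neural stem markers had a median of -0.999, Wnt genes -0.58 and forebrain genes 0.06.

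G1/S and DNA replication genes had a median of 0.26 with a camera adjusted p of 0.0660, and antigen presentation genes had 0.57 with 0.0927. Notch pathway genes had a median of -0.97, NF-kB targets, cytokines and chemokines -0.41, hedgehog pathway genes -0.35, interferon-stimulated genes -0.32 and JAK-STAT3 pathway genes -0.24. Medians were -0.19 for mesenchymal genes, -0.18 for cell cycle inhibitors and p53 targets, -0.09 for RAS-MAPK output genes, -0.06 for BMP receptors, ligands and antagonists, -0.02 for cholesterol synthesis genes, 0.00154 for collagens and matrix genes, 0.01 for ATF4 and unfolded protein response genes, 0.15 for immediate early genes and 0.26 for TGF-beta targets. Median and camera direction differed in sign for 5 lists, the ependymal, oligodendrocyte precursor, endothelial, TGF-beta and collagen lists, and mean and camera direction for 3, the ependymal, oligodendrocyte precursor and microglia lists. Inhba, which encodes an activin subunit, averaged 1.78 CPM in G328V and 28.1 CPM in WT, with 0.699 CPM in WT replicate 1.

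Nras and Eif2s3y were singled out after their values were seen. Nras had 1.45 to 1.68 counts per fragment in all 6 libraries, and 1.48% of 8924 genes had a mean as low. Eif2s3y, a Y-linked gene, had 2 counts in WT replicate 3 against 9979 and 9019 in the other WT libraries, while Ddx3y had 3119 there. The chromosome with the largest median deviation from its group was 14 in WT replicate 1, at -0.70 on the log2 scale.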
